A study of Echinococcus granulosus with 6 samples.

How the data were processed

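Protoscoleces of Echinococcus granulosus treated for 3 days with 100 µM dihydroartemisinin (DHA) or with 1% dimethyl sulfoxide (DMSO) were compared on 1-colour Agilent expression arrays, 3 arrays per group. The labels do not state the solvent content of the DHA samples, and they do not say whether samples of a group were separate cultures. Per the labels' protocols, cRNA was made from 0.5 µg of RNA by linear amplification and labelled with Cy3. The slides were read from the barcodes of the arrays: DMSO replicate 1 and DHA replicate 1 shared slide 1, and the other 4 arrays shared slide 2.

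The intensity values in the scanner output were made with Agilent Feature Extraction 11.5.1.1 per the file headers, while the submitters' processing notes name version 9.1. They are background-subtracted and detrended signals in arbitrary units, with no scaling between arrays. In the table from the authors, each array has an intensity column with 1 value per probe, and a log2 column that equals the log2 of that intensity minus the 75th percentile over the whole table. That table holds 10261 entries, 60 of them controls. Its log2 values differed from those computed here by 1 constant per array, between 0.00589 and 0.00643.

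Spots marked as non-uniform or population outliers, 1.50% to 2.56% of the gene spots on an array, were left out. The log2 signals of the remaining spots of a probe were averaged, and each array's 75th percentile over the 10201 analysed gene probes was subtracted. The array's 75th percentile lay between 9818 and 11122 signal units. A further 24 of the 10225 gene probes on the arrays carry no gene name and were not analysed here. A probe counted as well above background on an array when a share of more than 0.5 of its spots carried that scanner mark. Probes well above background on at least 3 of the 6 arrays, whatever the group, were tested, which left 9226. Gene identifiers, product names and scaffolds came from the authors' table. None of them was found in the reference annotation used (0 of its 11319 genes matched), so no coordinates are given. Of the 10201 probes, 7160 have a named product and 3041 do not. Some product names end in mid-phrase, such as acidic fibroblast growth factor intracellular, so a gene may be other than its name says.

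Groups were compared with limma 3.58.1 (lmFit and eBayes, no covariates) in R 4.3.3 (package data.table, version 1.17.8), two-sided, with Benjamini-Hochberg adjustment over the 9226 probes and a threshold of 0.05. The model had 4 residual and 3.48 prior degrees of freedom, and the median standard error of a log2 change was 0.083. Where a gene was above background in 1 group only, the fold is a lower bound: the mean of the bright group was set against the mean of the dim group after each dim value had been raised to the lowest signal that was well above background on its array. Probes well above background on all arrays of 1 group and on none of the other were counted separately.

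The tests, the 34 gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. The lists, 29 for pathways and 5 for cell types, are keyword patterns on product names, and all have at least 5 tested genes. Keywords also caught genes outside a list's meaning, such as the GINS protein PSF3 among splicing genes, RNA-directed DNA polymerases among replication genes, amyloid proteins among glycogen genes and a vacuolar ATP synthase among respiratory genes. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists by Benjamini-Hochberg.

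Named genes are the 12 largest rises and 12 largest falls among called probes with a named product whose arrays did not overlap between the groups, 1 per product name. To these were added up to 4 members of smallest p of each list that camera called and up to 2 called members of every other list. Up to 4 members came from the lists for antioxidant defence, calcium handling, glycolysis and tubulins, which have been discussed with artemisinins. The rule gave 96 genes, of which 1 is not reported here.

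Of the alternatives, all but normexp changed 1 choice at a time. They were quantile normalization, centring on the median, the authors' log2 values, no filter on background, a filter on all 6 arrays, blocks for replicate number and slide, slide 2 alone, an intensity trend, array weights and leaving out each array in turn. Added later were scaling to the E1A spike-in probes, and background correction by normexp with an offset of 50, which also put the median signals and local backgrounds of the spots in place of the processed signals. Leaving out each array for the count of probes on 1 side of the background was added later too. With slide as a random block the lists were tested with cameraPR on the blocked statistics. Probe sequences were compared with BLAST+ 2.17.0, and figures were drawn with Python 3.11.15.

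The steps were tested on simulated data in which 200 of 9226 probes were changed, 50 at each size. Of these, 60% were recovered at a log2 change of 0.5, 90% at 1, 98% at 2 and 100% at 3. Of the unchanged probes 8 were called (0.0891%), and the 1 shifted list of 45 genes was the 1 list called. In the simulation each probe varied independently and few probes changed, unlike the data below, where 54.7% of probes passed the threshold. Its share of false calls and its list result therefore do not carry over to them.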

Results

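Gene expression was measured in protoscoleces of Echinococcus granulosus, the dog tapeworm. Protoscoleces are the larval heads that form inside hydatid cysts and develop into the adult worm in the dog gut. The larvae had been kept for 3 days with 100 µM dihydroartemisinin (DHA) or with 1% of the solvent dimethyl sulfoxide (DMSO). DHA is the active form of the artemisinin antimalarials and carries an endoperoxide bridge that is opened by iron. Each group held 3 samples, and each sample was hybridised in 1 colour (Cy3) to its own array. The arrays lay on 2 slides. Slide 1 held DMSO replicate 1 and DHA replicate 1, and slide 2 held the other 4 samples. Each array carried 43803 spots for gene probes of 60 bases, 4 to 5 spots per probe and 1 probe per gene, and 10201 probes were analysed. Between 8995 and 9070 probes were well above background on the DMSO arrays and between 9161 and 9329 on the DHA arrays, and no gene spot was saturated. Across probes, arrays of one group correlated at r of 0.996 to 0.998, and arrays of different groups at 0.958 to 0.971. The labels do not say whether the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

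The comparison asks which genes of the larva change under DHA relative to DMSO. As the labels do not state how much DMSO the DHA samples held, a part of DMSO itself in the differences cannot be told apart. Of 9226 probes tested, 5047 (54.7%) changed at a Benjamini-Hochberg adjusted p below 0.05 in limma, 3050 of them higher and 1997 lower under DHA. Higher were 33.1% of the tested probes and lower 21.6%, and the counts given for gene lists below are to be read against these shares. Most changes were small: 981 probes changed at least 2-fold, 711 upward and 270 downward, and 99 rose and 8 fell at least 8-fold. The arrays of the groups did not overlap at 5923 probes (64.2%), where chance gives 10%. The first principal component held 91.1% of the variance and parted the groups. Among the tested probes, 138 were well above background on all DHA arrays and on no DMSO array, and 14 the other way round. Higher and lower are relative to each array's 75th percentile. On this scale 60.4% of the calls were higher, against 47.1% (2355 higher, 2641 lower) with quantile normalization. The share was 4.15% (337 higher, 7792 lower) when each array was scaled to its median over 7 E1A spike-in control probes, which rose by 0.45 to 1.14 log2 units under DHA (median 0.93, and 1.09 for the arrays' medians). Spike-in scaling moved the median of all probes to −1.06 log2, so the changes given here are changes relative to the bulk of the genes. Within slide 2, 4014 probes passed the threshold, and with slide as a block 5148. Slide 1, with 1 array per group, allows no test. Of the 4014 probes called on slide 2 alone, 3984 changed in the same direction on slide 1. The DHA arrays lay at later positions than the DMSO arrays on both slides. On slide 1 DMSO was at position 3 and DHA at 4, and on slide 2 DMSO was at 1 and 2 and DHA at 3 and 4. Agreement between the slides, or a slide block, therefore cannot separate treatment from position within a slide.

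**Figure D1:**
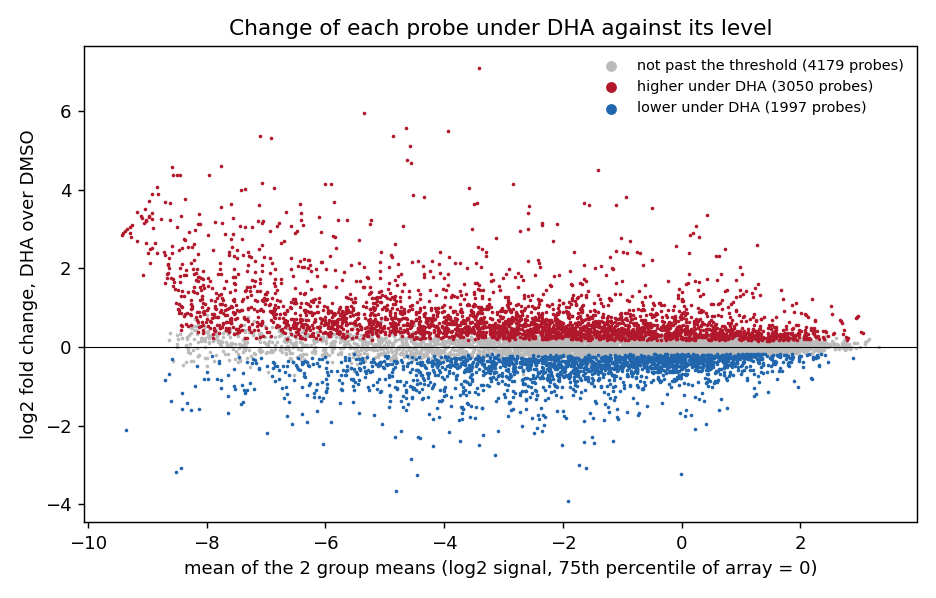
Each point is 1 of the 9226 tested probes: the x axis gives the mean of its group means (log2 signal, with each array's 75th percentile at 0) and the y axis the log2 fold change of DHA over DMSO (n = 3 arrays per group). The 3050 higher probes (red) reach larger changes than the 1997 lower ones (blue), most of all among dim probes on the left; with quantile normalization 2355 were higher and 2641 lower.

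The 12 largest fitted rises of genes with a named product included secreted, membrane and nucleotide-handling proteins. A gene annotated as WAP, kazal, immunoglobulin, kunitz and NTR (EgrG_001136800.1), domains found in secreted protease inhibitors, rose by 5.95 ± 0.11 log2 units (SE, n = 3 per group), or 61.6-fold, with an adjusted p of 3.41e-07 in limma (4.29 log2, or 19.5-fold, with normexp background correction). Its mean log2 level against the array's 75th percentile went from −8.33 ± 0.17 to −2.38 ± 0.16 (SD, n = 3). An ectonucleotide pyrophosphatase/phosphodiesterase (EgrG_001135700.1), an enzyme that cleaves nucleotides outside the cell, rose 22.8-fold (4.51 ± 0.10 log2). A threonine transfer RNA (EgrG_002064500.1) rose 17.8-fold (4.15 ± 0.32, but 2.86 with normexp) and a tetraspanin (EgrG_000355500.1), a membrane protein of cell surfaces, 14.1-fold (3.82 ± 0.22). The other 8 genes of this group were well above background on the 3 DHA arrays and on no DMSO array, so that only a lower bound can be given and their rank rests on signals near background. The bounds hold for the processed signals at the scaling used, and for the 14 genes of the fixed rule that have one the fold fitted with normexp was below it. With quantile normalization it was below the bound for an Hsp70 gene (EgrG_000331700.1, 3.12 against 3.22). The same held for a glucose carrier (EgrG_000853400.1, 5.26 against 5.66) and an alpha 1 tubulin (EgrG_000042200.1, 4.09 against 5.44). Some bounds of the 8 genes lie below measured rises outside the 12, such as the 12.4-fold of a glutathione S transferase (EgrG_000535200.1). Histone H4 (EgrG_000748300.1) was at least 21.0-fold higher, polyubiquitin (EgrG_000782900.1) at least 9.25-fold and early growth response protein 3 (EgrG_001006300.1), a zinc finger transcription factor, at least 7.42-fold. The bound was 5.27-fold for a beta 1,3 N galactosyltransferase (EgrG_000525000.1), which adds sugars to glycans, 5.09-fold for a class I fructose bisphosphate aldolase (EgrG_000993700.1) and 4.85-fold for EG95 (EgrG_000710400.1), the oncosphere antigen used as a vaccine in livestock. For a gap junction innexin (EgrG_000231100.1) it was 3.20-fold and for an alkaline phosphatase (EgrG_000752800.1) 2.91-fold.

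The 12 largest fitted falls included genes of muscle and of the extracellular matrix. A gene annotated as RPE spondin (EgrG_000199900.1) fell by 3.27 ± 0.18 log2 units (9.63-fold), with an adjusted p of 8.36e-06 in limma. Zasp (EgrG_000633900.1), a PDZ and LIM domain protein of the muscle Z disc, fell by 2.50 ± 0.09, and troponin I (EgrG_000734700.1), the inhibitory subunit of the thin filament, fell by 1.97 ± 0.13. Of the collagens, a fibrillar chain (EgrG_001060700.1) fell by 2.50 ± 0.13 and a type XI alpha 2 chain (EgrG_000524200.1) fell by 2.30 ± 0.09. A type II chain (EgrG_001060600.1), above background on 2 of the 3 DHA arrays, fell by 2.20 ± 0.19 (−1.0 with normexp, −2.87 with quantile normalization). A voltage gated potassium channel subunit (EgrG_000822300.1) fell by 2.30 ± 0.09 and the transcription factor annotated as sum (EgrG_001053100.1) fell by 2.15 ± 0.14. The gene trim56 (EgrG_000808400.1) fell by 2.14 ± 0.09, dihydropyrimidinase 2 (EgrG_000953200.1) fell by 2.13 ± 0.08 and an insulin growth factor binding protein (EgrG_000799300.1) fell by 2.10 ± 0.11. A heat shock protein with no size in its name (EgrG_000331600.1) was above background on the 3 DMSO arrays and on no DHA array, at least 3.09-fold lower.

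**Figure D2:**
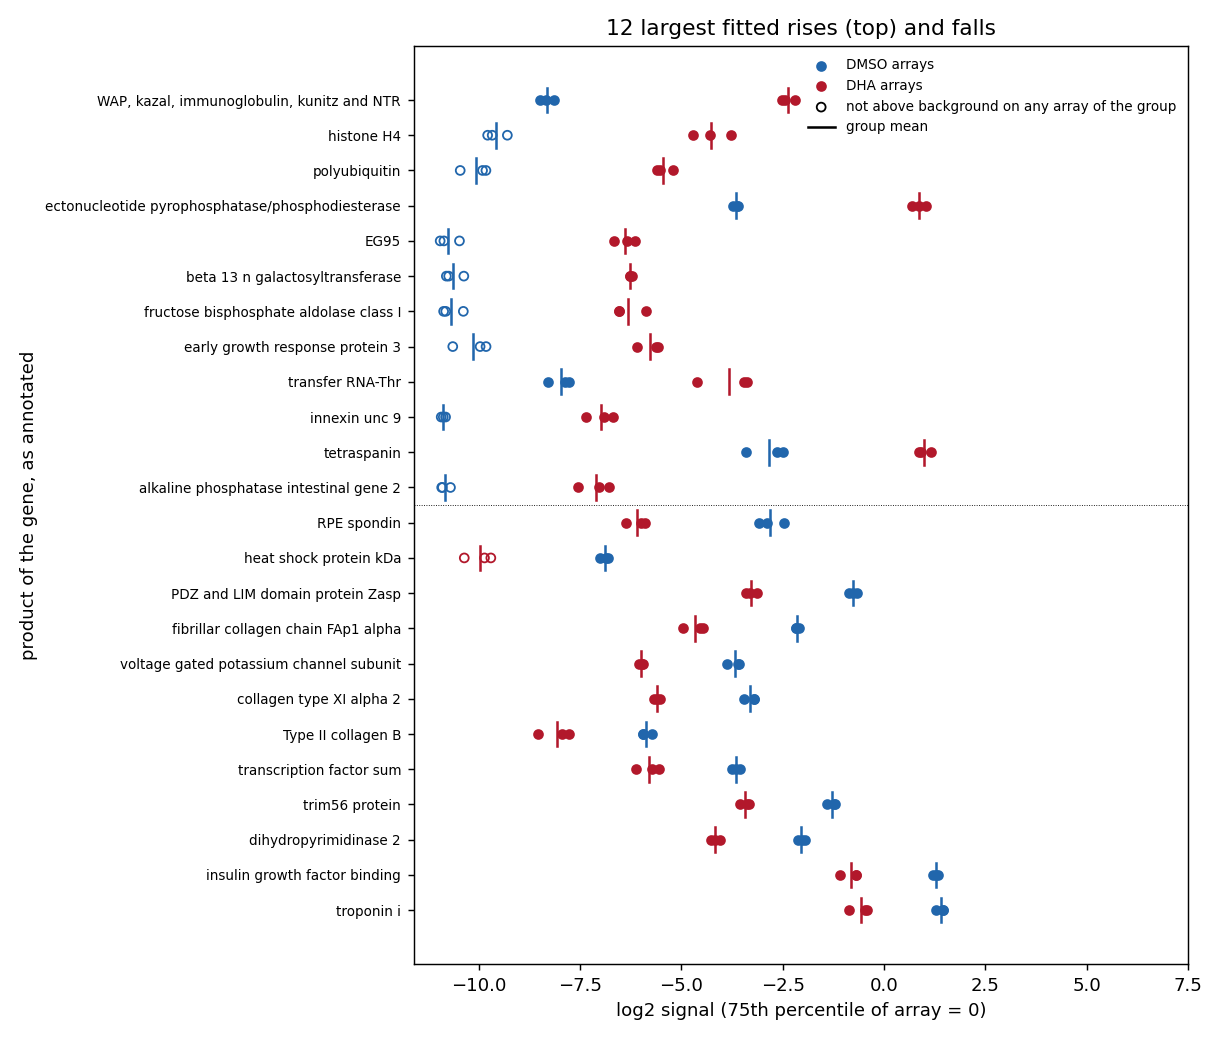
Log2 signal (x axis, each array's 75th percentile at 0) of the 12 largest fitted rises and the 12 largest fitted falls among genes with a named product (y axis), 1 point per array, 3 DMSO arrays in blue and 3 DHA arrays in red, with a bar at each group mean. Open points mark groups in which the probe was not above background on any array; for these genes only a bound on the fold is given, such as at least 21.0-fold for histone H4.

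Of 84 cytosolic chaperones and heat shock proteins, 49 rose, 9 fell and 26 did not pass the test (58 changed adjusted over the list alone), with a median change of 0.31 log2. The list passed limma's camera upward with an adjusted p of 0.0179, a call that was lost with an estimated correlation (adjusted p = 0.991 with an estimated correlation). A heat shock protein 90 (EgrG_000723800.1) rose 8.67-fold (3.12 ± 0.15 log2, but 1.97 with normexp), and 2 Hsp70 genes rose 4.24-fold (EgrG_000521000.1, 2.08 ± 0.07) and 2.22-fold (EgrG_000981800.1, 1.15 ± 0.06). A further Hsp70 gene (EgrG_000331700.1), above background only on the DHA arrays, was at least 3.22-fold higher. Its fitted rise of 2.54 was 0.92 with normexp and 1.64 with quantile normalization. The list's median was 0.31 within slide 1 and 0.32 within slide 2, with an adjusted p of 0.0187 in camera with slide as a block and 0.0190 within slide 2. In the endoplasmic reticulum list, 10 of 19 genes rose and 1 fell (11 adjusted over the list alone). RER1, a retention receptor (EgrG_000100000.1), rose by 0.60 ± 0.08 and the disulfide isomerase TMX3 (EgrG_001109600.1) fell by 0.65 ± 0.08. Of 45 proteasome genes, 18 rose and 3 fell (21 adjusted over the list alone). Activator subunit 3 (EgrG_000380200.1) rose 3.20-fold (1.68 ± 0.07), and an alpha subunit (EgrG_000864900.1) fell by 0.61 ± 0.07. Of 161 genes of ubiquitin conjugation and removal, 56 rose and 33 fell (89 adjusted over the list alone), close to the shares of all tested probes (33.1% higher and 21.6% lower). A ubiquitin gene (EgrG_001195600.1) rose 5.46-fold (2.45 ± 0.10). In the autophagy and mTOR list, 8 of 23 genes rose and 2 fell (9 adjusted over the list alone). The BECN1-regulating activator of autophagy (EgrG_001070200.1) rose 9.33-fold (3.22 ± 0.15, but 2.30 with normexp) and ribosomal protein S6 kinase alpha 3 (EgrG_000641400.1) rose by 0.60 ± 0.07. The endoplasmic reticulum, proteasome, ubiquitin and autophagy lists did not pass camera (adjusted p of 0.451, 0.4675, 0.738 and 0.738).

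Genes of redox defence and energy metabolism went both ways. Among 42 genes of the thioredoxin, glutathione and antioxidant list, 11 rose and 9 fell (20 adjusted over the list alone). A glutathione S transferase (EgrG_000535200.1), which joins glutathione to reactive compounds, rose 12.4-fold (3.63 ± 0.09 log2, adjusted p of 6.03e-07 in limma), a rise that was 2.26 log2 with normexp. The 2 genes named for a thioredoxin fold rose 3.85-fold (EgrG_001132900.1, 1.94 ± 0.13) and 2.57-fold (EgrG_000150600.1, 1.36 ± 0.07), and a glutaredoxin (EgrG_000226900.1) fell by 0.60 ± 0.06. Of 20 iron and haem genes, 2 rose and 4 fell (3 adjusted over the list alone). A cytochrome b5 domain protein (EgrG_000771700.1) rose by 0.38 ± 0.08, and the iron-sulfur scaffold NFU1 (EgrG_000603000.1) fell by 0.51 ± 0.10. Of 28 glycolysis genes, 11 rose and 9 fell (22 adjusted over the list alone). Lactate dehydrogenase A (EgrG_000608500.1) rose 9.97-fold (3.32 ± 0.07, but 2.26 with normexp) and a hexokinase (EgrG_000571500.1) 3.60-fold (1.85 ± 0.10), while a pyruvate kinase (EgrG_001035400.1) fell by 1.68 ± 0.09. The lactate dehydrogenase probe was dim, with a mean signal of 47.7 units under DMSO and 463 under DHA. The arrays' median signals lay between 2627 and 2959 units. Whether this probe reports the main lactate dehydrogenase transcript was not tested. The median change of the glycolysis list was −0.005 log2. The aldolase named above belongs here too. In the list of glycogen and glucose transport, 7 of 19 genes rose and 3 fell (10 adjusted over the list alone). A facilitated glucose carrier (EgrG_000853400.1), above background only on the DHA arrays, was at least 5.66-fold higher (but 5.26-fold fitted with quantile normalization), and phosphoglucomutase 2 (EgrG_001087500.1) rose 2.24-fold. Of 26 genes of the citric acid cycle and malate dismutation, 10 rose and 6 fell (19 adjusted over the list alone). An oxoglutarate dehydrogenase (EgrG_000429700.1) rose by 0.64 ± 0.08 and an NAD isocitrate dehydrogenase (EgrG_000537000.1) fell by 0.52 ± 0.07. In all, 7 of 61 genes of the respiratory chain and ATP synthase rose and 4 fell (8 adjusted over the list alone). A NADH ubiquinone oxidoreductase subunit (EgrG_000345800.1) rose by 0.49 ± 0.09 and a complex III subunit (EgrG_000880800.1) fell by 0.41 ± 0.06. Of 42 lipid carriers and related genes, 14 rose and 5 fell (18 adjusted over the list alone). Phospholipase D1 (EgrG_000249100.1) rose 6.20-fold (2.63 ± 0.09) and a high density lipoprotein receptor (EgrG_000478300.1) 2.46-fold.

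Of 64 mitochondrial ribosomal proteins, 18 fell, 4 rose and 42 did not pass (18 changed adjusted over the list alone), with a median change of −0.10 log2. The list passed camera downward with an adjusted p of 0.0179, a call that was lost with an estimated correlation (adjusted p = 0.991 with an estimated correlation). The large-subunit protein L2 (EgrG_000970050.1) fell by 0.51 ± 0.07, S35 (EgrG_001146500.1) fell by 0.43 ± 0.06 and S22 (EgrG_000822600.1) fell by 0.35 ± 0.06, while L45 (EgrG_000876400.1) rose by 0.42 ± 0.06. The list's median was −0.10 within slide 1 and −0.09 within slide 2, with an adjusted p in camera of 0.0187 with slide as a block. The call was also lost within slide 2 (0.0817), without DMSO replicate 1 (0.0616) and with quantile normalization (0.270), and over all alternatives the adjusted p ran from 0.0108 to 0.991. Cytosolic ribosomal proteins changed at few of 88 genes, 5 higher and 4 lower (8 adjusted over the list alone). The large-subunit protein L19 (EgrG_000772200.1) rose 2.65-fold, and a gene with an S1 RNA binding domain (EgrG_000967800.1) fell by 0.46 ± 0.07. The L19 probe had a mean signal of 563 units under DMSO and 1456 under DHA, below the arrays' median signals (2627 to 2959). The median change of the cytosolic ribosomal list was 0.03 log2. Of 54 translation factors, 10 rose and 6 fell (11 adjusted over the list alone). A gene annotated as eukaryotic translation initiation factor 2 alpha (EgrG_000183600.1) rose 2.47-fold. Another, annotated as ubiquitin associated translation elongation factor EF1B (EgrG_000961700.1), rose 2.14-fold. Their place among the translation factors rests on the keywords alone. Among 35 aminoacyl-tRNA synthetases, 10 rose and 4 fell (14 adjusted over the list alone). The synthetase for asparagine (EgrG_000889700.1) rose by 0.86 ± 0.07 and that for tryptophan (EgrG_000394100.1) fell by 0.57 ± 0.08. Of 80 splicing genes, 10 rose and 16 fell (23 adjusted over the list alone). Epithelial splicing regulator 1 (EgrG_001144100.1) rose by 0.58 ± 0.07, or 0.34 with quantile normalization. The GINS protein PSF3 (EgrG_000668400.1), a DNA replication factor caught by the keyword, fell by 0.80 ± 0.09.

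In the list of DNA replication and the cell cycle, 39 of 117 genes rose and 19 fell (54 adjusted over the list alone). A cyclin dependent kinase (EgrG_000659500.1) rose 2.28-fold, and activated cdc42 kinase 1 (EgrG_001089600.1), a signalling kinase caught by the keyword, 5.22-fold (2.38 ± 0.17). Of 17 histone genes, 9 rose and 3 fell (13 adjusted over the list alone). Besides histone H4, a histone H1 gamma (EgrG_000499100.1) rose 3.48-fold (1.80 ± 0.19). Among 55 genes of DNA repair, 23 rose and 8 fell (32 adjusted over the list alone). The recombination gene rad54 (EgrG_000375000.1) rose 2.26-fold. Apoptosis genes went both ways, with 11 of 34 higher and 9 lower (21 adjusted over the list alone). A death domain protein (EgrG_000054700.1) rose 7.76-fold (2.96 ± 0.14, but 1.85 with normexp), and caspase 8 (EgrG_000417900.1), an initiator caspase, fell by 0.72 ± 0.07. Of 35 genes on the list for germinative cells, the stem cells of the larva, 13 rose and 4 fell (17 adjusted over the list alone). The RNA-binding protein boule (EgrG_000963200.1), above background on 2 of 3 DMSO arrays, rose 8.44-fold (3.08 ± 0.09, but 1.77 with normexp), and musashi (EgrG_000070600.1) rose by 0.74 ± 0.07.

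Calcium handling genes split almost evenly, with 35 of 112 higher and 33 lower (72 adjusted over the list alone). A calcium transporting ATPase (EgrG_001008200.1), of the family of pumps that clear calcium from the cytosol, fell by 1.77 ± 0.10. A C2 calcium lipid binding protein (EgrG_001056800.1) fell by 1.80 ± 0.08 and a calcium binding mitochondrial carrier (EgrG_001045600.1) fell by 1.19 ± 0.06, whereas an EF hand protein (EgrG_000757500.1) rose 3.99-fold (1.99 ± 0.12, but 1.34 with normexp). Of 23 ABC transporters, the family of ATP-driven export pumps, 11 rose and 2 fell (13 adjusted over the list alone). A subfamily B gene (EgrG_000931700.1) rose 3.94-fold (1.98 ± 0.08) and a subfamily A gene (EgrG_000519900.1) 2.29-fold. In the MAP kinase and growth factor list, 25 of 89 genes rose and 22 fell (47 adjusted over the list alone). A gene annotated as acidic fibroblast growth factor intracellular (EgrG_001102200.1) rose 4.42-fold, and the small GTPase Rap 2a (EgrG_000254000.1) fell by 1.78 ± 0.09. Developmental regulators counted 29 of 77 higher and 17 lower (47 adjusted over the list alone). The list's members of smallest p, Wnt-5 (EgrG_000211300.1) and an antennapedia-type homeobox gene (EgrG_000984400.1), both fell by 1.44 (± 0.08 and ± 0.09). Of 20 peptidases, 8 rose and 5 fell (14 adjusted over the list alone). A leucyl aminopeptidase (EgrG_001031700.1) rose 5.21-fold and cathepsin L (EgrG_000654200.1), a lysosomal protease, 2.27-fold. Of 10 peptidase inhibitors, 4 rose and 1 fell (5 adjusted over the list alone). Next to the gene named above, a second WAP, kazal, kunitz and NTR gene (EgrG_001136500.1) was at least 9.94-fold higher.

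Of 44 muscle genes, 19 fell and 12 rose (31 adjusted over the list alone). A sarcomeric and another alpha actinin (EgrG_001096300.1 and EgrG_000219700.1), which tie actin filaments together, fell by 1.80 ± 0.08 and fell by 1.92 ± 0.10, the latter −1.24 with normexp. The muscle list did not pass camera (adjusted p of 0.192), and its median of −0.08 turned to 0.02 with normexp. Of 117 dyneins, kinesins and ciliary genes, 57 rose and 16 fell (79 adjusted over the list alone), and the list did not pass camera (adjusted p of 0.212). A dynein light chain (EgrG_000982000.1) rose 9.35-fold (3.23 ± 0.11, but 2.50 with normexp). A dynein heavy chain (EgrG_000725200.1) rose by 1.02 ± 0.06, or 0.43 with quantile normalization and 0.64 with normexp. The overlapping list for flame cells, the ciliated cells of the excretory system, had 23 of 42 genes higher and 3 lower (27 adjusted over the list alone), with an adjusted p of 0.110 in camera. Its member radial spoke 3 (EgrG_001158100.1) rose 2.49-fold. Of 31 tubulins, 14 rose and 5 fell (19 adjusted over the list alone). Alpha 1C (EgrG_000042700.1) and an alpha 1 chain (EgrG_000042200.1), above background only on the DHA arrays, were at least 2.70-fold and at least 5.44-fold higher. With quantile normalization the fitted fold of EgrG_000042200.1 was 4.09, below its bound. Another alpha 1 chain (EgrG_000040900.1) rose 2.01-fold, and beta 2C (EgrG_000202600.1) fell by 0.88 ± 0.06. Among 81 genes of the tegument, the worm's living surface, and of surface antigens, 36 rose and 20 fell (60 adjusted over the list alone). Besides EG95 and the tetraspanin a diagnostic antigen gp50 (EgrG_000261100.1) rose 3.60-fold (1.85 ± 0.09). Of 128 genes of the nervous system, 43 rose and 50 fell (97 adjusted over the list alone), the innexin and the potassium channel above among them.

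**Figure D3:**
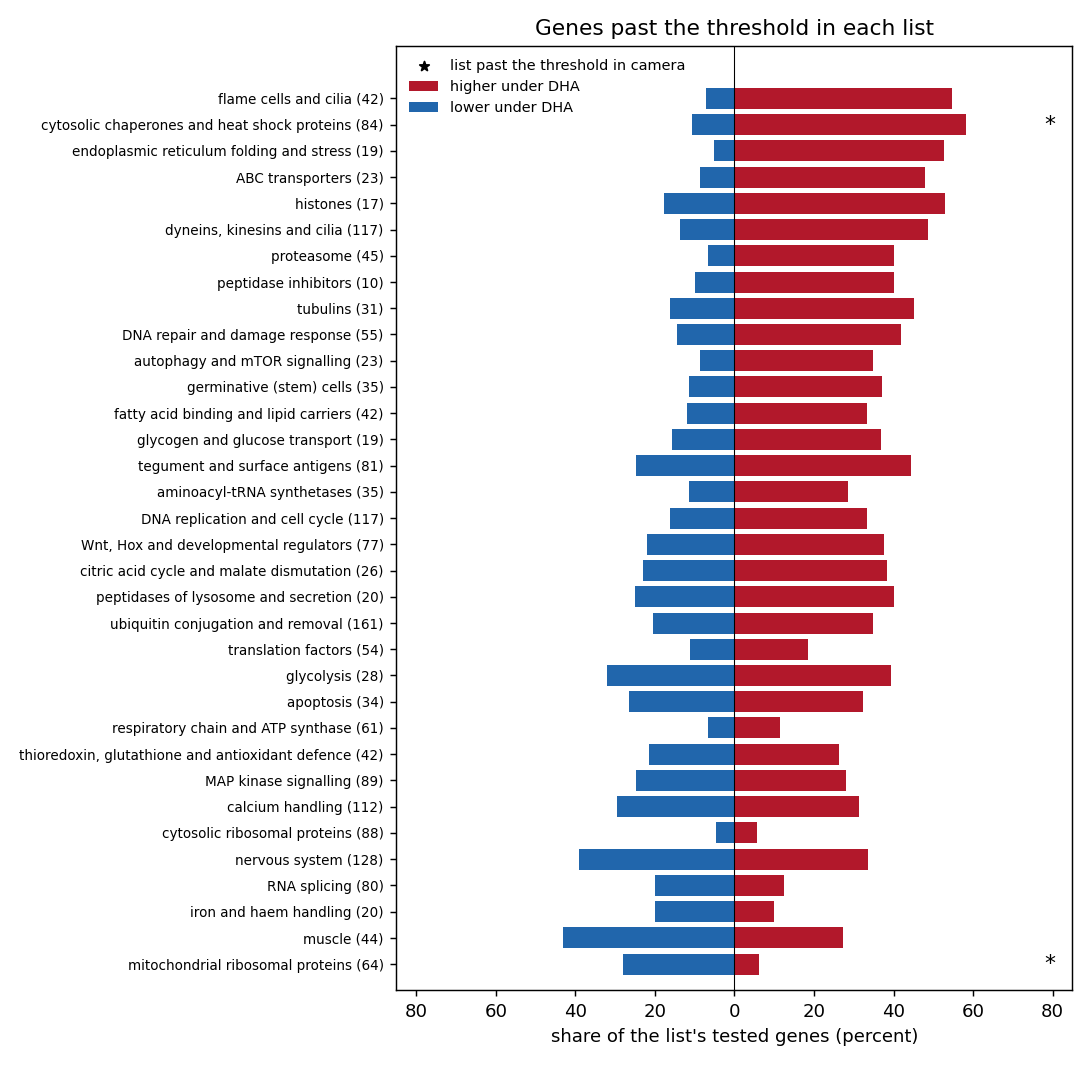
Share of each list's tested genes (x axis, percent, number of genes in brackets) that were higher (red, to the right) or lower (blue, to the left) under DHA at an adjusted p below 0.05 in limma. Stars mark the 2 lists past the threshold in camera, cytosolic chaperones (49 of 84 higher) and mitochondrial ribosomal proteins (18 of 64 lower), neither of which passed with an estimated correlation.

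Of the 34 lists, camera called 2, the chaperones and the mitochondrial ribosomal proteins, and 0 with an estimated correlation; the other 32 had adjusted p from 0.110 to 0.992. Limma's fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 27 lists, and its mixed test 34. In 11 lists the median, the mean and the camera direction differed in sign: iron, glycolysis, citric acid cycle, respiratory chain, cytosolic ribosomal proteins, translation factors, apoptosis, calcium handling, MAP kinase signalling, peptidases and nervous system. The sign of the median also turned under another scaling (median centring, quantile or normexp) in 13 lists: these except the citric acid cycle, and the synthetases, developmental regulators and muscle. The adjusted p of the 96 genes chosen by the fixed rule lay between 3.41e-07 and 0.00422 in limma. With normexp background correction the fold of 26 of them moved by over 1.5 times, all still past the threshold. For 12 of these the log2 change with normexp is given beside the fold, and the other 14 are the genes whose fold is given as a bound (histone H4 went to 2.76 log2, polyubiquitin to 2.02 and EG95 to 1.43). With quantile normalization the fold of 10 genes moved as much, 8 of them given as a bound. With normexp the number of probes changed at least 2-fold was 648 in place of 981.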

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

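The tests in this part were all chosen only after the result was seen.

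A signal outside the gene comparison differed between the groups. The E1A spike-in controls, transcripts added to each sample's RNA, were brighter on the DHA arrays. Over the 7 control probes above background on all 6 arrays, the rise was 0.45 to 1.14 log2 units per probe, with a median of 0.93. The arrays' median log2 signal over these probes, which 1 and the same probe gave on every array, rose by 1.09 (2.13-fold). It was 11.51, 11.92 and 11.97 on the DMSO arrays (SD 0.25) and 13.13, 13.09 and 12.44 on the DHA arrays (SD 0.39), so the groups did not overlap, which chance gives in 10% of comparisons of 3 with 3.

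A difference between the slides is argued against, since the arrays' medians rose by 1.62 within slide 1 and by 0.82 within slide 2, and the single probes by a median of 1.43 (0.71 to 1.62) and of 0.67 (0.32 to 0.91). Brighter labelling or scanning of the DHA arrays as a whole is argued against as the only cause, since the 75th percentile of the gene probes differed by −0.037. Together with less worm transcript per unit of RNA it would give the same values, so a part in the rise stays open. Of the causes considered, it stays open whether DHA larvae held less transcript per unit of RNA, which would be biological. Unequal amounts of spike-in mixed in, which would be technical, stay open as well. These cannot be told apart, because no separate measure of input was used here and the exact two-sided permutation p of 0.1 is the smallest that 3 arrays against 3 can give. If the former held, most transcripts may have fallen in amount per unit of RNA, since spike-in scaling gives 7792 lower and 337 higher probes. The amount per larva would not follow from this, because the spike-in was added to RNA. Other causes were not tested.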

How the results depend on the processing

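The normexp and spike-in alternatives, and leaving out arrays for probes on 1 side of the background, were chosen only after the data had been seen; the others were planned. The number of changed probes was 5047, and it lay between 4014 (slide 2 alone) and 5333 (intensity trend) under every alternative except spike-in scaling. Leaving out 1 array gave 4338 to 4788 changed probes, 2653 to 2954 higher, 1639 to 1904 lower, 882 to 1046 changed at least 2-fold, and 159 to 208 on 1 side of the background only (152 with all arrays, 124 with the scanner's less strict mark). By construction the count on 1 side of the background cannot fall when an array is left out, since fewer arrays must meet the condition. The authors' log2 values gave 5047 again, a void comparison since they differ from those used by 1 constant per array. Quantile normalization gave more lower (2641) than higher (2355) probes, unlike the 1997 and 3050 reported, and moved the median of all probes from 0.06 to −0.03.

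With spike-in scaling 8129 probes changed, 337 higher, 7792 lower and 5423 at least 2-fold. The cause is its construction: it moves every change by −1.12, so rises smaller than this turn into falls. With normexp 648 probes changed at least 2-fold. Its offset of 50 pulls the ratios of dim probes towards 0 by construction; whether this is the whole cause was not tested.

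The number of lists called, 2, was 1 with quantile normalization, 1 within slide 2, 1 to 2 when an array was left out (1 without DMSO replicate 1), 3 with spike-in scaling, 0 with camera at an estimated correlation and 27 with fry, which asks another question. The chaperones had adjusted p from 0.00321 to 0.991 in limma over the alternatives and were lost with the estimated correlation alone; the mitochondrial ribosomal proteins had 0.0108 to 0.991 and were lost with quantile normalization (0.270), within slide 2 (0.0817), without DMSO replicate 1 (0.0616) and with the estimated correlation. Slide 2 alone and leaving out an array use fewer arrays. For the other losses the cause was not tested. Of the single list results, fry and spike-in scaling not included, 641 stayed on their side of the threshold and 5 fell short of it. Neither called list changed direction, but the median changed sign in 13 lists that were not called. All 1712 fits of named genes kept side and direction, spike-in scaling not included. These genes were chosen from the same data for large changes or small p, so this was largely fixed in advance. Of the 5047 calls of the main fit, 4377 were called again with quantile normalization and 3932 within slide 2.

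The values do not show whether the replicate numbers pair the samples: deviations from the group mean correlated across probes at 0.39, 0.06 and −0.13 for equal numbers, and DMSO 3 was closest to DHA 2 (0.29). The pair at 0.39 was the highest of all pairs and also shared slide 1. With 3 arrays per group these correlations cannot rule pairing out. With replicate number as a block, 4855 probes changed, 2966 higher and 1889 lower. Planned but not run were normexp on mean signals, which are not used here, and averaging probes per gene, since each gene has 1 probe. Signal over background limits the 152 probes with a bound in place of a fold.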

Other observations

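The gene families, the collagens and the scaffold region below, and the tests of added background and of a response that depends on brightness, were chosen only after the result was seen.

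Collagens went both ways. Falls went beyond the 3 chains named in the report: an alpha 2(I) chain (EgrG_000823800.1) fell by 1.80 ± 0.07 log2 units (SE, n = 3 per group), a type IV chain (EgrG_000144350.1) fell by 1.38 ± 0.09, a chain named for types I, II, III, V and XI (EgrG_001190600.1) fell by 1.27 ± 0.10 and a type V chain (EgrG_000144300.1) fell by 1.15 ± 0.13. The falls of another type V chain (EgrG_000203400.1, −0.63) and of type XV (EgrG_000729300.1, −0.51) were smaller. In contrast a type XXVIII chain (EgrG_000549400.1) rose by 0.75 ± 0.07, while another (EgrG_000548800.1, 0.13 ± 0.07) did not pass the test. Rises also came from type VI chains (EgrG_001137200.1, 1.12 ± 0.13, above background on 1 of 3 DMSO arrays, and EgrG_001137400.1, 0.48 ± 0.08) and a gene annotated as vertebrate collagen (EgrG_001136600.1, 1.79 ± 0.10). These directions held with median centring, quantile normalization and normexp, but the rise of EgrG_001137200.1 shrank to 0.28 with quantile normalization and 0.54 with normexp. Another type IV chain (EgrG_000417600.1) went from 0.28 to −0.16 with quantile normalization. With spike-in scaling, which lowers every change, EgrG_001136600.1 stayed at 0.67, EgrG_001137200.1 showed no change, and EgrG_000549400.1 and EgrG_001137400.1 became −0.38 and −0.65.

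A stretch of scaffold pathogen_EgG_scaffold_0006 held several of the strongest rises. Besides the ectonucleotide pyrophosphatase/phosphodiesterase named in the report, 3 further genes of that name rose by 3.61 ± 0.16 (EgrG_001135600.1), 3.62 ± 0.15 (EgrG_001135800.1) and 3.53 ± 0.14 log2 units (EgrG_001136200.1), and another (EgrG_001135900.1), not above background on any DMSO array, was at least 1.58-fold higher. Both WAP genes of the report follow in the order of the identifiers, with a collagen-like gene (EgrG_001136600.1, 1.79 ± 0.10) between them. A gonadotropin beta subunit (EgrG_001137500.1), not above background on any DMSO array, was at least 2.32-fold higher. Its change fitted with normexp was 0.96 log2 units, below that bound. Within the stretch, RNA binding protein 12 (EgrG_001136300.1) did not pass the test (0.08 ± 0.07), a hypothetical protein (EgrG_001137100.1) fell by 0.40 ± 0.11, and the type VI collagen chains above rose less. None of these genes has a probe similar to another probe (at least 40 of 60 identical bases), and the called ones kept their direction with median centring, quantile normalization and normexp.

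Among 37 product names shared by at least 8 tested genes, 74 two-sided Fisher's exact tests with Benjamini-Hochberg adjustment asked which differed from other probes in their share of higher or of lower calls. Of 24 genes named Hsp70, 20 rose and 3 fell (adjusted p of 2.04e-05, median 0.74). Of 16 dynein heavy chains, 13 rose and 0 fell (adjusted p of 0.00192, median 0.45), and of 9 diagnostic antigens gp50, 8 rose and 1 fell (adjusted p of 0.0133, median 0.77). The medians were 0.64, 0.29 and 0.73 with quantile normalization, and −0.39, −0.68 and −0.35 with spike-in scaling, which moved the median of all probes to −1.06. Genes named as hypothetical proteins had 608 rises and 329 falls among 1419 (adjusted p of 4.22e-15), with a median of 0.20 that became −0.01 with quantile normalization, and of 446 expressed conserved proteins, 124 rose and 138 fell (adjusted p for the falls of 7.08e-05, median −0.02). These were the 5 names that passed. Genes are not independent replicates, so these p-values describe calls, not samples.

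Dim probes rose more than bright ones: with probes ordered by signal into 10 equal bins, the median change in the dimmest bin was 0.56 log2 units, with 559 probes higher and 106 lower, and in the brightest bin it was 0.04. Added background on the DHA arrays is argued against, since 0.53 of the 0.56 was left when the largest gain of the negative control spots, 1.67 signal units, was taken off every DHA signal. The floor of the measurement is argued against, since among dim probes above background on all 6 arrays 81.3% of calls were higher, against 56.8% in the other bins. An array response that depends on brightness stays open: the 2 dim spike-in probes rose by 0.18 more than the 3 middle ones (1.12 and 0.94) and the 2 bright ones by 0.55, so the rise was smaller in brighter controls, over too few probes to decide. Activation of genes that are nearly silent in DMSO larvae may be the biological alternative, also open, and quantile normalization, which makes the arrays' distributions equal, takes the median of the dimmest bin to −0.08.

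Neighbouring genes changed alike: across 7112 pairs of genes adjacent in identifier order on a scaffold, the changes correlated at Spearman's rho of 0.136 and Pearson's r of 0.133, a correlation across genes, which are not independent replicates. In 10000 shuffles within scaffolds the highest rho was 0.057, so the permutation p is 0.0001, the smallest they can give, here and in the tests below. Similar probes are argued against as the whole cause (rho of 0.134 without such pairs), as are neighbours of 1 product name (0.123 over 6752 pairs of different names) and alike signal levels (0.129 for changes relative to the median of each signal bin). Over the pairs of different names Pearson's r was 0.097. Names were compared as written, so related neighbours with names spelled differently could stay in. Probes were compared with probes only, not with transcripts. Related neighbouring genes are therefore only partly covered by these tests. Regulation shared by neighbours, with a part in the rise of the stretch above, is a candidate explanation that was not tested.

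Splitting the 6 arrays into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 5047 changed probes, 3050 higher, 1997 lower and 981 changed at least 2-fold, and the highest other split gave 0 for each, so 1 of 10 splits reached each count. Every other split mixes the groups and so puts the difference between them into the spread within its sets. As the component that parted the groups held 91.1% of the variance, the 0 was largely fixed in advance. It is therefore no measure of what chance gives. For gene lists the real split gave 2 and the highest other 6 (DMSO 1, DMSO 3 and DHA 3 against the rest), and 4 of 10 splits gave at least 2.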
